A study of Ziziphus nummularia with 2 samples.

How the data were processed

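RNA from whole seedlings of one genotype of Ziziphus nummularia was sequenced in 2 libraries, 1 from a control seedling sample at 0 MPa and 1 from a drought sample at -0.3 MPa. Per the labels' protocols, RNA was taken up in Trizol reagent and the libraries were built with an Illumina TruSeq kit. How the water potential was set, how long it was held, and how many seedlings went into each sample are not given in the sources used here. The aligner Bowtie2 is named in the submitters' processing notes without a version or role. The assembler, the counting program, and any filter on contigs are not given in the sources used here.

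Each deposited table lists the same 98230 contigs, which are assembled stretches of transcript named by a number. The read counts per contig were deposited by the authors as whole numbers, not normalized. The FPKM values (reads per 1000 bases of contig and scaled by the read total of the library) were also computed by the authors, per the file headers. Dividing a contig's count by its FPKM gave a whole multiple of 1 constant per library, within 0.01 of a base, for all 92739 contigs with a read in the control library and all 86040 in the drought library. With the smallest step taken as 1 base, this gave the length of 97409 contigs and the library total behind the FPKM values. The lengths from the 2 libraries were equal for all 81370 contigs that had reads in both. The totals were 30922631 for the control and 18689979 for the drought library, larger than the 12509371 and 7406331 reads listed on contigs (40.5% and 39.6% of those totals). Whether the totals count single reads and the contig values count read pairs is not given in the sources used here, and a different choice would not change the ratio between libraries. The lengths of the 821 contigs without a read in either library were not found, and these contigs enter only the alternative without a filter on low values, at 0 in both libraries.

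The files give no gene name, description, or sequence for the contigs, and no genome or annotation was used here. The gene lists chosen before the data were examined, for drought and other functions, could therefore not be matched to contigs, and no gene or pathway is named. Contigs that are alleles, splice forms, or near-identical copies of one gene could not be grouped, so a read that fits several of them may have been listed on any one. No strand setting is known.

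The ratio of a contig was log2((drought FPKM + 1)/(control FPKM + 1)), with a pseudocount of 1 FPKM, which understates the change of low contigs. Contigs with at least 1 FPKM in one library were kept. With 1 library per group there is no spread between replicates, so no p-value was computed and a fixed rule of size was used instead: a contig was counted as higher or lower when the ratio was at least 2 or at most -2, that is 4-fold on this scale. Size of the difference, not significance, is what these counts report. Named contigs are the 2 with the highest and the 2 with the lowest ratio among those kept, with ties broken by mean FPKM and then by number. Before the data were examined, this rule, the threshold, the pseudocount, the filter, and the alternatives were fixed, except where the closing section says otherwise.

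Counting error was measured by simulation. The reads of each contig were pooled and dealt back to the 2 libraries in proportion to their totals, 100 times, which gives library pairs that differ by chance in counting alone. Intervals are 95% intervals: Wilson for shares, exact (Clopper-Pearson) binomial for ratios of 2 counts, and exact Poisson for a single count. A count of 0 allows up to 3 reads, a one-sided 95% limit, and lower bounds on a fold against a count of 0 use this limit. The plan, made for FPKM values alone, gave no fold against a 0, so these bounds are an addition to it. Reads carry no molecular identifiers, so intervals on reads cover counting error only. Intervals on shares of contigs, on ratios of such shares, and on medians across contigs treat contigs as independent draws. Contigs of one gene could not be grouped, so these may be too narrow. No interval here says anything about variation between seedlings. One read on a contig of 200 bases is worth 0.162 FPKM in the control and 0.268 FPKM in the drought library, and on a contig of 1000 bases 0.0323 and 0.0535 FPKM.

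The size rule was tested on simulated data of 97409 contigs in which 100 were raised and 100 lowered by a known fold. The changed contigs were drawn from those with at least 5 FPKM in the pooled reads, so recovery of lower contigs was not tested. The rule called 21 and 24 of the changed contigs at a true 4-fold change, 100 and 99 at 8-fold, and 100 and 100 at 16-fold, none in the wrong direction. Among the other contigs it called at most 3. The alternatives were other pseudocounts, filters, thresholds, and 3 scalings: each library brought to the same sum over contigs (TPM scale), drought values divided by the median ratio of the 19932 contigs with at least 5 FPKM in both libraries, and each library divided by its upper quartile over contigs above 0. Summing contigs per gene was planned and could not be run, because the contig numbers do not show which contigs share a gene. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, and matplotlib 3.10.9.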

Results

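Ziziphus nummularia is a thorny wild jujube shrub of dry regions. The data compare its whole-seedling transcriptome under a normal water supply (0 MPa) and under drought (-0.3 MPa), with 1 library for each condition. A more negative water potential means that water is harder for the plant to take up. Because neither condition has a replicate, every difference given here is a difference between 2 libraries, has no replicate check, and carries no p-value.

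The control library held 12509371 reads on contigs and the drought library 7406331. The assembly held 98230 contigs, of which 92739 (94.4%) had at least 1 read in the control and 86040 (87.6%) in the drought library. The contigs were short. Their median length was 275 bases, the N50 (the length at or above which contigs hold at least 50% of the bases) was 592 bases, and 76.4% were under 500 bases, while the longest reached 14949 bases. At least 1 FPKM was reached by 50139 contigs in the control and 49341 in the drought library, and at least 100 FPKM by 925 and 1050 contigs.

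The first question was how far the drought transcriptome lay from the control. Of the 59206 contigs with at least 1 FPKM in one library, 1935 (3.27%) were at least 4-fold higher and 1801 (3.04%) at least 4-fold lower in the drought library. With the pseudocount of 1 FPKM, most contigs, 41353 or 69.8%, differed by less than 2-fold. The pseudocount understates the change of low contigs, and 9009 kept contigs had a mean under 1 FPKM. Larger differences were more often upward: 221 contigs were at least 16-fold higher and 112 at least 16-fold lower, and 39 were at least 64-fold higher against 7 lower. At 16-fold the excess of higher contigs had the same direction under 3 other scalings (to an equal sum, by the median ratio, and by the upper quartile), with 198 to 272 higher and 112 to 145 lower. At 4-fold it did not, since scaling by the upper quartile gave 1741 higher and 1949 lower contigs. The 4-fold counts also depend on the pseudocount, with 5759 higher and 6079 lower at 0.1 FPKM and 721 and 488 at 5 FPKM. The 16-fold and 64-fold counts were not taken at other pseudocounts, so their upward excess holds for a pseudocount of 1 FPKM only.

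The 4-fold contigs carried a visible part of each library. Those higher in drought took 10.4% of the drought reads on contigs (95% interval 10.37% to 10.41%) and 1.06% of the control reads (1.05% to 1.06%). Those lower in drought took 11.3% of the control reads (11.30% to 11.33%) and 1.49% of the drought reads (1.479% to 1.496%). These contigs were chosen for their difference in the same reads, so the shares describe how much of each library they make up. Contigs in the higher set had a median length of 302 bases and those in the lower set 334 bases, against 333 bases for all kept contigs.

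The median log2 ratio of drought over control was -0.06 across the kept contigs, with quartiles at -0.70 and 0.60 and 5th and 95th percentiles at -1.68 and 1.66. Across contigs, which are not independent replicates, the 2 libraries had a Pearson correlation of 0.777 on the log2(FPKM + 1) scale and a Spearman correlation of 0.726. Library pairs simulated with counting error alone had a mean correlation of 0.977 and a mean interquartile range of 0.31, against the observed 1.29. In these pairs the rule called a mean of 0.06 contigs higher and 0.34 lower, and never more than 1 and 3. The numbers of 4-fold contigs thus lay far above counting error, and the variation between seedlings of one condition was not measured.

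**Figure D1:**
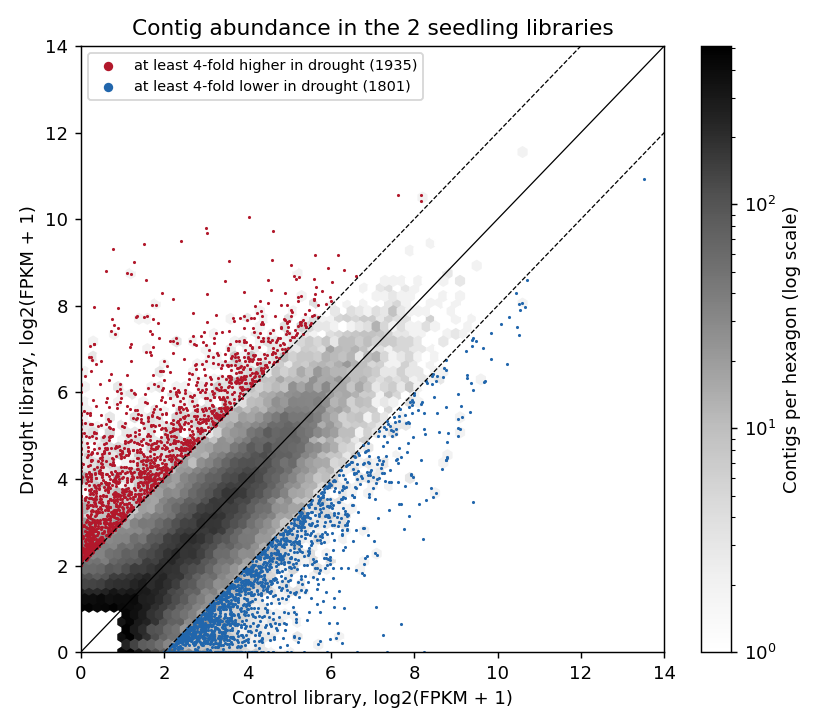
Each kept contig is placed by log2(FPKM + 1) in the control (horizontal axis) and the drought library (vertical axis). Grey hexagons show the number of contigs on a log scale, the solid line marks equal values and the dashed lines 4-fold, and the coloured points are the 1935 contigs at least 4-fold higher (red) and the 1801 at least 4-fold lower (blue) in drought.

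The 4 contigs with the most extreme ratios had many reads in one library and few or none in the other. Contig 433713, of 184 bases, had 4 reads (0.703 FPKM) in the control and 2174 reads (632 FPKM) in the drought library, an 899-fold higher value (95% counting interval 351 to 3303) and a log2 ratio of 8.54 with the pseudocount. Contig 548886, of 546 bases, had 9 control and 4556 drought reads, or 0.533 and 446 FPKM, which is 838-fold higher (441 to 1833). In the other direction, contig 446197, of 198 bases, had 1835 reads (299.7 FPKM, 286 to 314) in the control and none in the drought library. Taking 3 reads as the limit that a count of 0 allows in this library, it was at least 369.7-fold lower. Contig 533993, of 430 bases, had 2158 control reads (162 FPKM, 156 to 169) and no drought read, which makes it at least 435-fold lower by the same limit.

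Contigs present in only one library were the next group examined. In the control library 1383 contigs had no read while reaching 1 FPKM in drought, and 1784 contigs had no read in drought while reaching 1 FPKM in the control. Most of these rest on few reads: the median was 6 reads in the drought library and 11 in the control, and 73.2% and 49.2% of them had at most 10. Counting error alone gave a mean of 160 and 237 such contigs, at most 192 and 280 in any simulated pair. A smaller set was deep. There were 46 contigs with at least 100 control reads and no drought read, and 25 with at least 100 drought reads and no control read, against 0 in each direction in every simulated pair. A minimum of 100 reads is reached at a lower FPKM in the deeper control library, so 46 and 25 say nothing about direction. With at least 5 FPKM in the other library, the order turned, with 128 contigs lacking a read in the control and 99 in drought. Depth differed between the libraries, and absence of a read does not show absence of the transcript.

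The most abundant contigs differed strongly between the libraries. Of the 100 contigs with the highest FPKM, 37 were shared, and of the highest 1000, 487 were shared, where simulated unchanged pairs shared a mean of 99 and 966. Of the 100 highest in the control, 36 were at least 4-fold lower in drought and 0 were higher. Of the 100 highest in drought, 30 were at least 4-fold higher and 2 were lower. Ranking by one library favours contigs that are high in it, so these counts describe the lists only.

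The highest contig of the control library, 374 bases long and singled out after its values were seen, had 135022 reads or 11675 FPKM (95% counting interval 11613 to 11737), 1.08% of all control reads on contigs. In drought it had 13680 reads and 1957 FPKM, 5.97-fold lower (5.86 to 6.07). The highest contig of the drought library, 161 bases long, had 3203 FPKM there (3139 to 3268) and 2631 FPKM in the control (2586 to 2677), a 1.22-fold difference (1.19 to 1.25). The 10 highest contigs held 3.79% of the summed FPKM in the control and 2.98% in drought. The 100 highest held 12.6% and 10.3%, and the 1000 highest 33.3% and 30.5%. Without the single highest contig of each library, the 10 next held 2.502% in the control and 2.75% in drought, so that the order of the libraries turned at this level. Counted in reads, which long contigs collect more of, the order was the opposite for the highest 10 but not for the highest 100. The 10 contigs with the most reads took 4.95% of the reads on contigs in the control (95% interval 4.94% to 4.96%) and 6.08% in drought (6.06% to 6.10%), and the single highest took 1.08% and 2.08%. The 100 with the most reads took 13.33% in the control (13.32% to 13.35%) and 13.17% in drought (13.15% to 13.20%).

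The share of contigs at least 4-fold apart differed with abundance. Among contigs with a mean of 5 to 10 FPKM it was 8.52% (95% interval 7.97% to 9.11%, 9202 contigs), among those of 50 to 100 FPKM 17.2% (15.4% to 19.1%, 1548 contigs), and among those of 100 to 500 FPKM 22.8% (20.2% to 25.6%, 916 contigs). In the 57 contigs above 500 FPKM it was 31.6% (21.0% to 44.5%). Contigs under a mean of 1 FPKM cannot reach 4-fold with this pseudocount. The direction also differed by class. From 50 to 100 FPKM, 178 contigs were higher and 88 lower in drought, an excess that kept its direction under all 3 other scalings (160 to 220 higher, 89 to 116 lower, in classes of 1478 to 2209 contigs). From 100 to 500 FPKM the numbers were 108 and 101, and scaling by the upper quartile turned them to 92 and 107 of 867 contigs. Above 500 FPKM, 4 contigs were higher and 14 lower of 57. The 3 other scalings gave 4 to 7 higher and 14 to 21 lower there, in classes of 54 to 101 contigs.

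**Figure D2:**
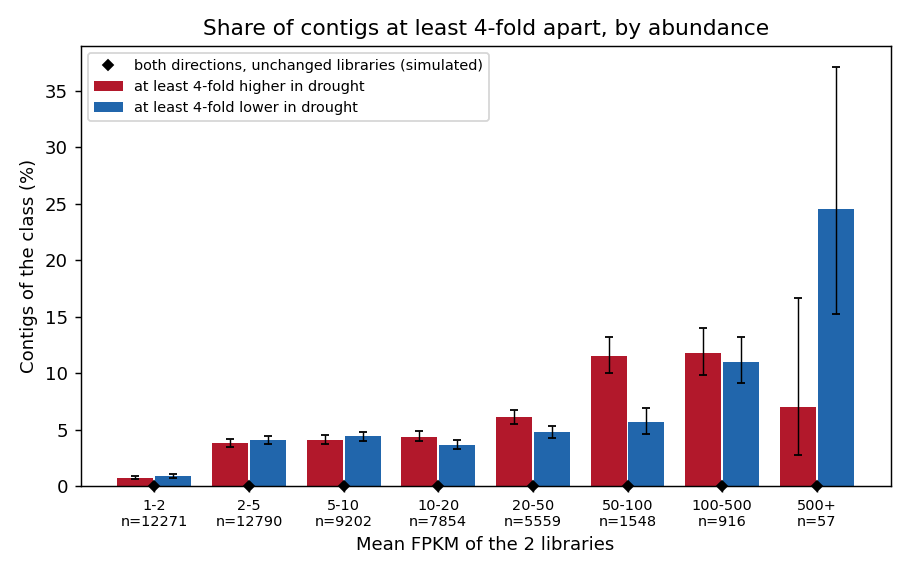
Bars give the percentage of contigs at least 4-fold higher (red) and lower (blue) in the drought library, by class of mean FPKM, with 95% Wilson intervals and the number of contigs under each class. Black diamonds give the share expected from counting error alone, which is at or near 0 in every class, while the 2 bars of a class add up to 8.52% at 5 to 10 FPKM, 22.8% at 100 to 500 FPKM, and 31.6% above 500 FPKM.

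Long contigs sat slightly lower in the drought library than short ones. The median log2 ratio was 0.01 for the 11925 kept contigs of 150 to 199 bases, -0.09 for the 11731 of 500 to 999 bases, -0.21 for the 1572 of 2000 to 4999 bases, and -0.23 for the 68 of 5000 bases or more. Large differences were rarer in long contigs. At least 4-fold differences were found in 6.73% of the shortest class (95% interval 6.29% to 7.19%), in 2.54% of contigs of 2000 to 4999 bases (1.87% to 3.45%), and in 0 of the 68 longest, which allows a share of up to 5.35%. These shares were not compared at equal abundance. The share of 4-fold contigs itself differed with abundance, so the part of length alone is not known. The difference in medians between the shortest contigs and those of 2000 bases or more kept its direction under the 3 other scalings. That is no check of the trend, because a scaling moves the log2 ratios of all contigs by nearly the same amount.

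**Figure D3:**
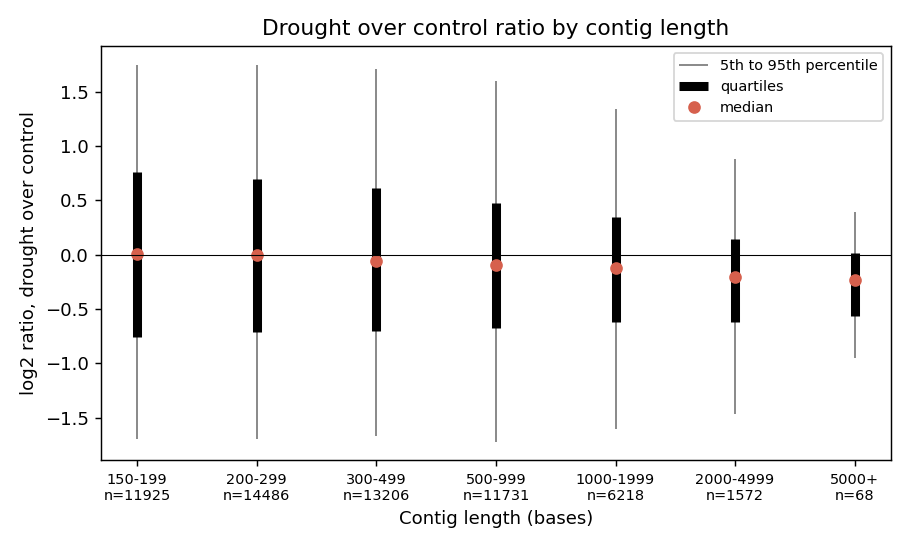
The log2 ratio of drought over control is shown by contig length in bases, with the median (orange point), the quartiles (thick bar) and the 5th to 95th percentile (thin line) of each class, and the number of contigs below. The median moves from 0.01 in the shortest class to -0.23 in the longest, and the spread narrows.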

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

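Thinning of control reads to the drought total and a minimum of 50 reads in one library were chosen after seeing the data; the other alternatives here were planned. The 4-fold counts depended most on the pseudocount: 5759 contigs were higher and 6079 lower with 0.1 FPKM, and 721 higher and 488 lower with 5 FPKM. With thresholds of 2-fold and 8-fold they were 8272 and 9581, and 635 and 447, since a threshold sets the count by construction. All other filters and scalings, thinning (1945 higher, 1804 lower) and the 50-read minimum (1424 and 1518) left both counts within 1.5 times, yet the excess of higher contigs turned with 0.1 FPKM, with the 2-fold threshold, and with the upper quartile (1741 and 1949); the cause was not tested. The order under the 50-read minimum says nothing about direction, since a minimum on raw reads removes contigs higher in the shallower drought library more readily. Upper-quartile scaling shifted all drought values by -0.10 on the log2 scale. The median log2 ratio stayed below 0 throughout: it was -0.0757 with 0.1 FPKM, -0.0338 with 5 FPKM, -0.0347 with a minimum of 5 FPKM, -0.0362 on the TPM scale, -0.17 with the upper quartile, and -0.0802 after thinning. The interquartile range was 0.597 with 5 FPKM. Contigs without a read in one library numbered 4670 (control) and 11363 (drought) at a minimum of 0.1 FPKM in the other, and 128 and 99 at 5 FPKM, where the order of the libraries turned. Without the highest contig, the 10, 100 and 1000 highest held 2.502%, 11.3% and 32.3% of the control FPKM and 2.75%, 9.92% and 30.3% of the drought FPKM. The correlation was 0.672 with 0.1 FPKM, 0.850 without a filter, and 0.726 as Spearman's. Without the filter all 98230 contigs entered in place of 59206, among them the 821 contigs at 0 in both libraries. The 4 named contigs kept their direction and stayed past 4-fold in all 20 values, which their choice as the most extreme ratios made nearly certain. No paired analysis was possible because each condition has 1 library, and for the same reason no replicate was left out and no other split of the samples was drawn. Depth limits the low contigs: 3 reads on 200 bases correspond to 0.485 FPKM in the control and 0.803 FPKM in the drought library.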

Other observations

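All tests in this part were chosen after their results or related results had been seen, except the simulation of counting error. In addition, 3 long and abundant contigs stood out by nearly equal values. They were 2766, 1903 and 941 bases long, and had 1441 to 1491 FPKM in the control and 2876 to 2987 FPKM in the drought library, each 1.995- to 2.043-fold higher in drought. Together they took 2.04% of the control reads on contigs (95% Wilson interval 2.03% to 2.05%) and 4.201% of the drought reads (4.19% to 4.22%). A candidate explanation is that they are pieces or forms of one molecule, 5610 bases in sum, which would have nearly one value per library. Chance was compared by random pairing of control and drought values among the 57 contigs with a mean of at least 500 FPKM. Of 10000 pairings, a share of 0.0332 held 3 contigs as close (within 3.87% in both libraries), and the first 1000 alone had given 0.0539. The share and the set depend on the minimum: it was 0.0295 at 700 FPKM and 0.0020 at 1000 FPKM, with 2000 pairings each, and at 400 FPKM another set of 3 was the closest. This decides nothing. The pairings break the link between the 2 values of a contig, which choosing contigs by their mean also sets (Pearson correlation -0.11 of log2 values across the 57), and the set was noticed before it was tested. Sequences, which would decide it, were not used here.

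The share of 4-fold contigs rose with abundance, although more reads should bring less counting error. Counting error alone gave 0 such contigs at a mean of 100 to 500 FPKM in 100 simulated pairs, against the observed 209. The pseudocount and low read numbers do not account for it either. With 0.5 read added in its place, and contigs with at least 100 reads expected at their mean FPKM, the share was 23.3% at 100 to 500 FPKM and 10.5% at 5 to 10 FPKM, a ratio of 2.21 (95% interval 1.93 to 2.54). Contig length was held between 500 and 999 bases in a further test, and the ratio was 2.10 (1.56 to 2.83). The classes were set by the mean of the 2 values that also make the ratio. A contig high in 1 library alone can thus enter a high class, and no test here removed that effect. Also open are a response of abundant transcripts to drought, a difference between the seedlings sampled, and reads that moved between near-identical contigs. With 1 library per condition and no sequences, these could not be tested.

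The lower ratios of long contigs remained with 0.5 read in place of the pseudocount and the same minimum on expected reads. This minimum admits short contigs only at higher FPKM than long ones, so the test does not separate low read numbers from abundance. Under both settings, the median of the 1623 contigs of 2000 bases or more differed from that of the 9386 contigs of 200 to 499 bases by -0.28 (95% bootstrap interval -0.31 to -0.23). Abundance may account for part of it: averaged within 5 classes from 5 to 500 FPKM and weighted by the number of long contigs, the difference was -0.14 (-0.20 to -0.09), and without the 2 highest classes, which held 7 and 6 long contigs, it was -0.13 (-0.19 to -0.08). The class of 5 to 10 FPKM carried most of this, with -0.17 over 595 long contigs, against -0.07 over 255 at 10 to 20 FPKM and -0.01 over 82 at 20 to 50 FPKM. The interval of the average reaches past the bound of -0.1 set for ruling abundance out. Long contigs outside 5 to 500 FPKM are not in the average, so -0.14 and -0.28 do not rest on the same contigs. A first version of this test, with a minimum of 100 summed reads, gave -0.00084 (-0.06 to 0.05). It was replaced after its result was seen, because summed reads favour contigs that are high in the deeper control library: the median of short contigs at 5 to 10 FPKM was -0.23 under it and -0.02 under the minimum used here. A length bias of one library preparation and a response of the plants cannot be told apart here, because either would give the rank correlation of -0.0899 between length and ratio across 26172 contigs and each condition has 1 library. This correlation used the same minimum on expected reads and was not adjusted for abundance, which may account for part of it too.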
